A study of Homo sapiens with 12 samples.

How the data were processed

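Circular RNAs (circRNAs) were profiled by sequencing of rRNA-depleted total RNA in directional libraries, per the labels' protocols. The 12 libraries came from 2 human colorectal cancer cell lines, HCT116 and Lovo (the labels' spelling), each as the parental, drug-sensitive line and as a derivative selected for resistance to 5-fluorouracil. Each of the 4 groups held 3 libraries. Groups and replicate numbers were taken from the labels. The labels do not state whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which can be technical. Nor do they state whether the resistant libraries of a line came from separate selections. Differences of a derivative from its parent that are unrelated to resistance therefore cannot be told apart from resistance in the contrasts.

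The deposited table holds raw counts of back-splice junction reads per circRNA and library, per the file headers, with no normalization. The authors' table also gives, per the file headers, the position, strand, host gene, class and circBase identifier of each circRNA and the length of its predicted sequence. Human genome build hg19, cutadapt 1.9.3, STAR 2.5.1b and edgeR 3.16.5 are named in the submitters' processing notes with no role. The circRNA caller, the annotation and the minimum for listing a circRNA are not given in the sources used here. Positions are printed 1-based on hg19, as the circRNA identifiers in the table write them. No genome sequence was used here. Of 5957 host gene identifiers in the table, 5302 matched a current human gene symbol and 5605 a current or older symbol, and names are printed as the table gives them. The table lists 22 circRNAs with no host gene, which entered every circRNA test but no host gene sum or list.

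The table lists 17938 circRNAs, of which 14911 had at least 1 read in the 12 libraries, 3027 had none and 1221 had a highest count of 1. By class, 14140 were exonic, 2673 sense overlapping, 1064 intronic, 39 antisense and 22 intergenic. A circBase identifier was given for 11172 of them (62.3%). Junction reads per library ranged from 5654 to 10535. The low depth limited testing to 300 circRNAs (1.67% of the table, from 254 host genes), which held 23.7% to 29.3% of the reads of a library. Ratios of reads summed over a group are given with exact conditional binomial 95% intervals scaled by effective library size. Where a group had 0 reads, the fold is printed as at least the lower limit of this interval, taken for the higher over the lower group. Intervals and these limits cover counting error only, since reads without molecular identifiers are not independent molecules.

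Changes were tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts: TMM scaling, filterByExpr with a minimum count of 5 and a minimum total count of 15, and the quasi-likelihood F-test (glmQLFit, glmQLFTest). All 12 libraries entered 1 fit with 4 group means and 8 residual degrees of freedom. The contrasts were resistant against sensitive in HCT116, the same in Lovo, the difference of these 2 effects, and sensitive HCT116 against sensitive Lovo. A call needed a Benjamini-Hochberg adjusted p under 0.05 over the features tested. The same test was run on counts summed over all circRNAs of a host gene. The standard error printed beside a log2 fold change is the size of the change divided by the square root of its F statistic. Levels are CPM of junction reads after TMM scaling (the cpm function of edgeR), as mean ± SD.

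For each line, 17 lists of host genes were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01) where at least 5 circRNAs of the list were tested, with an estimated correlation and fry beside it. The lists were fluoropyrimidine and folate metabolism; ABC transporters; mismatch and base excision repair; DNA damage response and strand break repair; p53 and apoptosis; cell cycle; WNT signalling; EMT, adhesion and extracellular matrix. Further lists were chromatin modifiers, splicing and circRNA biogenesis factors, rRNA processing with RNA decay and modification, receptor, RAS-MAPK and PI3K-mTOR signalling, TGF-beta and BMP signalling, and markers of intestinal epithelium, fibroblasts, immune cells and endothelium. Because 2 lists alone held at least 5 tested circRNAs, the reads of all circRNAs of a list were also summed per library and tested in edgeR. This was chosen after seeing the data. The sums were scaled by total counts without TMM, unlike the circRNA and host gene tests. Chromosomes, and the part of 18p ending below 15 Mb, were tested as sets in the same way.

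Library measures were compared between resistant and sensitive libraries with two-sided exact permutation tests, for which 3 against 3 libraries cannot go below p = 0.1. For numbers of circRNAs detected, each library was thinned to the smallest total, 5654 reads, by its hypergeometric expectation. Agreement between the lines was measured by correlations across circRNAs, which are not independent replicates. The planned Fisher's exact test on shared calls is not used here, because with 0 calls in Lovo its result was fixed. Libraries of 1 group were compared in pairs by a chi-square test over circRNAs with at least 10 reads in the pair. All 12 pairs differed by more than read sampling alone, so none was the same reads listed again, but the test cannot tell repeat preparations of 1 culture from separate cultures.

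Apart from what the text marks as added or as not fixed beforehand, the comparisons, tests, gene lists, alternatives and the rule for naming circRNAs were fixed before the data were examined. Under that rule, up to 8 circRNAs per direction and line were named if they passed the threshold, changed at least 2-fold, had non-overlapping groups and lay above the median level. Where fewer passed, the smallest p-values filled the list up to 4 per direction, said not to pass. Also named were circRNAs called in the same direction in both lines, the 6 with the smallest p for the difference between the lines, and the host genes with the most calls. The rule added the 3 smallest p-values of the 2 lists and 2 chromosomes with the smallest camera p, and 5 per direction between the parental lines. A fixed list of circRNAs by circBase identifier and circRNAs of TYMS, DPYD, UMPS, TYMP, ENOSF1 and ABCB1 completed it. Other circRNAs named below were chosen after their values were seen, and the text says so.

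The test procedure was tested on simulated data in 20 runs per comparison, with negative binomial counts drawn for the circRNAs of the table from their mean levels, the library sizes and the common dispersion (0.153 for circRNAs). In each run 30 circRNAs, drawn from the 300 tested in the real data, were changed by 2-, 4- or 8-fold, in both directions. The shares recovered therefore hold for circRNAs as abundant as those tested, and not for the rest of the table. With 17938 circRNAs simulated for HCT116, the test recovered 3% of these 2-fold, 38.5% of 4-fold and 67% of 8-fold changes, and 6 of 223 calls were false. For Lovo, 3.5%, 28.5% and 61% were recovered, with 4 false among 190 calls. For the difference between lines, 2%, 9% and 28.5% were recovered, with 4 false among 83 calls. For the parental lines, 2.5%, 27.5% and 58.5% were recovered, with 3 false among 180 calls. An 8-fold increase was recovered in 98% of cases for HCT116 and 93% for Lovo, and an 8-fold decrease in 36% and 29%. On 5957 simulated host gene sums, with changes again placed only in those tested in the real data, 4.75%, 37.4% and 69.7% of 2-, 4- and 8-fold changes were recovered for HCT116 (12 of 438 calls false), and 3%, 29.7% and 64.0% for Lovo (12 of 380 false). A list shifted 2-fold was found by camera in 14 of 20 runs for HCT116 and 17 of 20 for Lovo, a chromosome in 17 and 18 of 20, and 4-fold shifts of either kind in 20 of 20. All these shifts were upward, and of the lists only the 2 with at least 5 tested circRNAs were shifted. The test of summed reads was not simulated, so these shares do not cover the other lists.

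Alternatives were DESeq2's size factors and total counts in place of TMM, a minimum count of 10, no filter, the DESeq2 1.42.0 and limma-voom tests, the replicate number as a block, each of the 12 libraries left out, fits of the 6 libraries compared, and an unadjusted p under 0.05 with a 2-fold change. For sets they were the estimated correlation and 1 circRNA per host gene, and for library measures detection at 2 counts, no thinning and shares of circRNAs in place of reads. Added after seeing the data were merging junctions of 1 strand with both ends within 5 bases and thinning the HCT116 libraries to the Lovo totals in 20 draws. A predicted length and a disease annotation in the table were not used here, and linear RNA was not analysed here.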

Results

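Back-splice junction reads, which mark circular RNAs, were counted in 2 colorectal cancer cell lines and in derivatives of both that survived 5-fluorouracil (5-Fu), a fluoropyrimidine that blocks thymidylate synthesis. The resistant cells had been grown in doses raised stepwise from 0.1 to 2 μg/ml and survived at least 3 days at the last dose, per the labels. Junction reads per library were 6238, 8836 and 10535 in sensitive HCT116, 9623, 7894 and 8822 in resistant HCT116, 6739, 5896 and 5654 in sensitive Lovo, and 7568, 6994 and 7438 in resistant Lovo. By reads pooled over all libraries the most abundant circRNA was a junction of FAT1, which encodes a cadherin-family adhesion protein (hsa_circ_0001461, chromosome 4, 187627717 to 187630999, 611 reads). Those of the kinase gene HIPK3 (526 reads) and of XPO1, a nuclear export receptor (461 reads), followed. The FAT1 circRNA stood at 7953 ± 1199 CPM in sensitive and 9048 ± 424 CPM in resistant HCT116, and at 4455 ± 289 and 4788 ± 1295 CPM in Lovo (SD, n = 3 each). The order differed by line. In Lovo that of HIPK3 stood higher than FAT1, at 6147 ± 1047 CPM in sensitive and 7707 ± 1504 CPM in resistant cells. In HCT116 that of ARHGAP12 (6277 ± 1411 and 7901 ± 730 CPM) lay above those of HIPK3 and XPO1. FAT1 and XPO1 were singled out after their values were seen.

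The lines differed far more than their drug response. The first principal component held 40.5% of the variance and separated HCT116 from Lovo, while the second held 9.76%. On the second component the sensitive HCT116 libraries lay between 4.61 and 5.11, and the resistant ones at -10.2, -3.03 and -1.67, with resistant replicate 1 apart from the others. The Lovo states lay apart the other way, the sensitive libraries between -2.68 and -1.29 and the resistant ones between 0.646 and 3.66. Resistant Lovo libraries held 7333 ± 301 junction reads against 6096 ± 570 in sensitive Lovo (SD, n = 3 each, exact permutation p = 0.1, the smallest that 3 against 3 allows), and HCT116 libraries 8780 ± 865 against 8536 ± 2164 (exact permutation p = 1). After thinning every library to 5654 reads, 2608 ± 12.7 circRNAs were detected in resistant and 2459 ± 142 in sensitive Lovo (n = 3 each, exact permutation p = 0.1). At 2 counts per circRNA this difference turned to -69.1, from 149.3 at 1 count, so its direction rests on circRNAs seen by single reads. In HCT116 the thinned numbers were 2697 ± 177 and 2687 ± 296 (n = 3 each, exact permutation p = 0.9). That difference also turned, from 10.1 to -49.2, at 2 counts. Exonic circRNAs held 85.9 ± 0.891% of reads in resistant and 86.8 ± 1.37% in sensitive HCT116, and 88.3 ± 0.887% and 87.4 ± 0.870% in Lovo (n = 3 each, exact permutation p = 0.4 in both lines). Intronic circRNAs held 3.31 ± 0.473% in resistant and 4.06 ± 0.555% in sensitive Lovo (n = 3 each, exact permutation p = 0.1). The 10 most abundant circRNAs took 5.21 ± 0.0283% of reads in resistant against 4.68 ± 0.324% in sensitive HCT116, and 5.11 ± 0.253% against 4.55 ± 0.182% in Lovo (n = 3 each, exact permutation p = 0.1 in both lines).

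The comparison of resistant with sensitive HCT116 asked which circRNAs accompany 5-Fu resistance in that line. The circRNA of CYP24A1, the enzyme that inactivates active vitamin D, was nearly lost: it fell by 3.84 ± 0.58 (SE) on the log2 scale, from 110 junction reads in the 3 sensitive libraries to 8 in the 3 resistant ones. Its level was 4677 ± 815 CPM in sensitive and 312 ± 55.4 CPM in resistant cells (SD, n = 3 each). The circRNA of ARHGAP5 rose by 2.89 ± 0.65 log2 units, from 400 ± 82.4 to 3005 ± 814 CPM (9 to 77 reads). The circRNA of EPB41L5, a membrane-associated FERM-domain protein with a known part in epithelial-mesenchymal transition, rose by 2.14 ± 0.57 log2 units, from 557 ± 430 to 2668 ± 646 CPM (14 to 68 reads). In each of the 3 circRNAs the libraries of one state all lay above those of the other, and these were all the calls among 300 tested (2 higher, 1 lower).

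The edgeR quasi-likelihood adjusted p was 1.63e-08 for CYP24A1 (hsa_circ_0060927, chromosome 20, 52773708 to 52788209, exonic), 0.00129 for ARHGAP5 (hsa_circ_0031584, chromosome 14, 32559708 to 32586493, exonic) and 0.0165 for EPB41L5 (hsa_circ_0008278, chromosome 2, 120885264 to 120932580, sense overlapping). An unadjusted p under 0.05 was met by 30 circRNAs, where chance gives 15. In counts, CYP24A1 was 15.2-fold lower in resistant cells (95% counting interval 7.44 to 36.0). The call of CYP24A1 held in all 15 alternatives run for it. ARHGAP5 lost its call without resistant replicate 1 (2.66, edgeR adjusted p = 0.0727) and without a filter on low counts (edgeR adjusted p = 0.0676), over a range of 2.92e-05 to 0.0727 in 15 alternatives. EPB41L5 passed in 9 of 15 alternatives, with adjusted p from 0.0023 to 0.668. It missed in edgeR without sensitive replicate 1 (0.173) or 2 (0.182), without resistant replicate 1 (0.222) or 2 (0.0998), without a filter (0.668), and in DESeq2 (0.0552). The number of calls was 1 without resistant replicate 1 and 5 without resistant replicate 3.

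**Figure D1:**
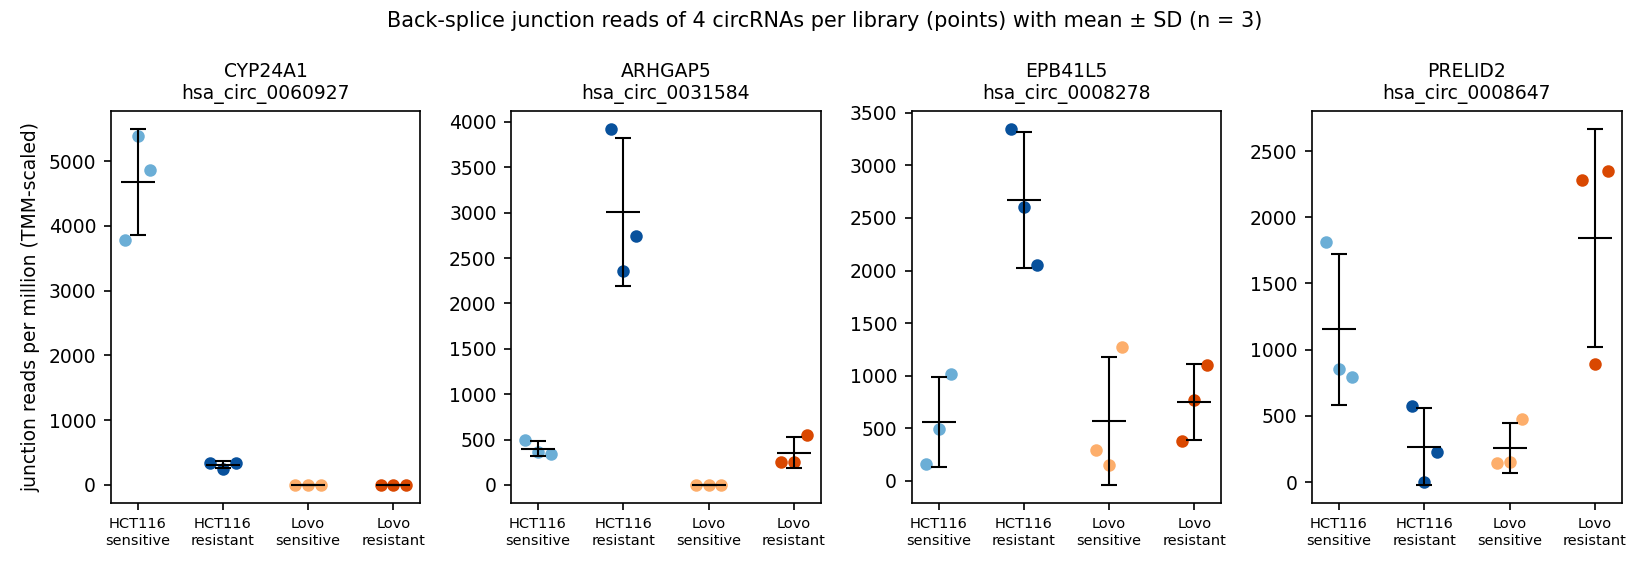
CPM of junction reads (TMM-scaled, vertical axis) of 4 circRNAs in each library (points) of the 4 groups, with mean and SD (bars, n = 3). In HCT116 the CYP24A1 circRNA is lower and the ARHGAP5 and EPB41L5 circRNAs are higher in all 3 resistant libraries than in any sensitive one, while the CYP24A1 circRNA has 0 reads in all Lovo libraries.

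Summing all circRNAs of a host gene gave the same 3 genes, which is no separate support, since the sums include the called junctions. These held 110 of the sensitive CYP24A1 reads, 77 of the resistant ARHGAP5 reads and 68 of the resistant EPB41L5 reads. CYP24A1 fell by 3.82 ± 0.59 log2 units (115 to 8 reads, edgeR adjusted p = 5.51e-08), ARHGAP5 rose by 2.51 ± 0.50 (17 to 104 reads, edgeR adjusted p = 0.000169) and EPB41L5 rose by 1.79 ± 0.44 (26 to 91 reads, edgeR adjusted p = 0.0114). They were the calls among 580 host genes tested (37 at unadjusted p under 0.05, 29 by chance). Next came WHSC1, which encodes a histone methyltransferase also called NSD2 (-1.47 ± 0.42, 85 to 31 reads, edgeR adjusted p = 0.0742) and the deubiquitinase gene USP34 (1.20 ± 0.37, 54 to 135 reads, edgeR adjusted p = 0.119). Neither passed.

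Several circRNAs in HCT116 stood close to the threshold without passing. A USP34 junction with no circBase record (chromosome 2, 61483519 to 61552592) had 23 reads in sensitive and 89 in resistant cells (log2 fold change 1.71 ± 0.52, edgeR adjusted p = 0.0755, range over 15 alternatives 0.001 to 0.668). It passed in 5 alternatives, among them the one without sensitive replicate 1 (2.74, edgeR adjusted p = 0.00501), and had 0 reads in Lovo. The WHSC1 circRNA hsa_circ_0008460 had 25 and 2 reads, 13.8-fold lower (counting interval 3.44 to 120, edgeR adjusted p = 0.129, range over 13 alternatives 0.03 to 0.668), and passed in limma-voom (adjusted p = 0.03) and in edgeR without resistant replicate 3 (0.0364), which held both resistant reads. A junction assigned to HLA-C that runs from HLA-C to the paralogous HLA-B region (chromosome 6, 31238163 to 31323269), and whose reads are therefore uncertain, had 5 and 24 reads (2.03 ± 0.70, edgeR adjusted p = 0.18). It passed without resistant replicate 3 (2.54, edgeR adjusted p = 0.0303, range over 14 alternatives 0.0303 to 0.892). Its log2 fold change ranged from 1.10 to 2.54 in these, and 16 of the 24 resistant reads were in resistant replicate 1. The circRNA of RREB1, a RAS-responsive transcription factor, had 9 and 37 reads (1.87 ± 0.68, edgeR adjusted p = 0.196, range over 14 alternatives 0.068 to 0.892). Of the 37, 22 were in resistant replicate 1. That of SAMD4A, an RNA-binding translational repressor, had 9 and 0 reads, at least 2.18-fold lower (edgeR adjusted p = 0.196).

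In Lovo no circRNA passed the test, so the resistance comparison there gives values and no named change. The edgeR quasi-likelihood test called 0 of 300 circRNAs, with 17 at an unadjusted p under 0.05 where chance gives 15, and DESeq2 and limma-voom also called 0. The smallest p belonged to the circRNA of PRELID2, a PRELI-domain protein (hsa_circ_0008647, chromosome 5, 145176005 to 145205763, exonic), with 5 reads in sensitive and 42 in resistant cells (2.78 ± 0.77 log2, n = 3 each, edgeR adjusted p = 0.0992). It passed when the 6 Lovo libraries were fitted alone (2.65, edgeR adjusted p = 0.0144) and after merging junctions with ends within 5 bases, an alternative chosen after seeing the data (2.89, edgeR adjusted p = 0.0477), over a range of 0.0144 to 0.855 in 15 alternatives. Leaving out any 1 library gave 0 calls in Lovo.

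The ARHGAP5 circRNA that rose in HCT116 was at 0 reads in sensitive Lovo and at 2, 2 and 4 reads in the resistant Lovo libraries, at least 1.47-fold higher (edgeR quasi-likelihood adjusted p = 0.566 over all tested). Among the 3 circRNAs called in HCT116, taken as a list after its calls were seen, its edgeR quasi-likelihood adjusted p in Lovo over these 3 was 0.0138. The ARHGAP5 host gene sum had 6 and 14 reads in Lovo (0.97 ± 0.76, edgeR quasi-likelihood adjusted p = 0.95). EPB41L5 had 11 and 17 reads in Lovo (0.40 ± 0.69), without passing there either in its host gene sum (15 and 37 reads, 1.06 ± 0.53) or joined with a junction ending within 5 bases (1.28 ± 0.56, an alternative chosen after seeing the data). CYP24A1 had 0 reads in all 6 Lovo libraries. Other Lovo circRNAs with small p-values were those of ATP5C1, a subunit of mitochondrial ATP synthase (27 and 68 reads, 1.12 ± 0.41), ZNF800 (0 and 12 reads, at least 2.40-fold higher), MAN1A2, a Golgi mannosidase (12 and 1 reads, 13.9-fold lower, counting interval 2.06 to 595), RARS, the arginyl-tRNA synthetase (15 and 2 reads, 8.70-fold lower, 2.02 to 78.4), and ERBB2IP (52 and 25 reads, -1.26 ± 0.52). The edgeR adjusted p of these 5 lay between 0.566 and 0.567. On host gene sums edgeR also called 0 of 580 (30 at unadjusted p under 0.05, 29 by chance, smallest adjusted p 0.564), as did DESeq2 and limma-voom, and 1 without sensitive replicate 1. ATAD2, with 0 and 11 reads, and PRELID2, with 36 and 98 reads (1.20 ± 0.39), had the smallest p-values.

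Of 300 circRNAs, the 1 whose change between sensitive and resistant cells differed between the lines was that of PRELID2. It had 25 and 7 reads in sensitive and resistant HCT116 but 5 and 42 in Lovo. In CPM it went from 1153 ± 571 to 268 ± 290 in HCT116 and from 258 ± 189 to 1843 ± 822 in Lovo (SD, n = 3 each). The difference of the effects was -4.75 ± 1.09 log2 units (edgeR quasi-likelihood adjusted p = 0.0038), and 29 circRNAs had an unadjusted p under 0.05 where chance gives 15. The call was lost without sensitive HCT116 replicate 1 (-4.35, edgeR adjusted p = 0.074), without resistant Lovo replicate 3 (-4.54, 0.0678) and without a filter (-4.78, 0.0776), over a range of 0.000807 to 0.0776 in 20 alternatives. The host gene sum of PRELID2 differed by -2.03 ± 0.57 (edgeR adjusted p = 0.104), and 0 of 580 host genes passed (40 at unadjusted p under 0.05). For the difference between the lines DESeq2 called 1 circRNA and limma-voom 2.

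WHSC1 came next, with 25 and 2 reads in HCT116 against 2 and 14 in Lovo (edgeR adjusted p = 0.0562, range over 19 alternatives 0.00989 to 0.536). It passed in limma-voom (adjusted p = 0.024) and in edgeR without sensitive HCT116 replicate 2 (0.0209), resistant HCT116 replicate 3 (0.0112), sensitive Lovo replicate 1 (0.00989) or resistant Lovo replicate 2 (0.0125). Both sensitive Lovo reads were in replicate 1. The host sum of WHSC1 over 16 circRNAs differed by -2.49 ± 0.63 (edgeR adjusted p = 0.0517). The circRNA of YTHDF2, a reader of N6-methyladenosine, had 31 and 10 reads in HCT116 and 14 and 35 in Lovo (-2.80 ± 0.93, edgeR adjusted p = 0.193). That of NUP205, a nuclear pore protein, had 26 and 12 against 4 and 21 reads (-3.35 ± 1.19, edgeR adjusted p = 0.292, range over 19 alternatives 0.0188 to 1) and passed without sensitive Lovo replicate 1 (edgeR adjusted p = 0.0188), which held all 4 sensitive Lovo reads. The HLA-C junction differed by 2.69 ± 0.82 (edgeR adjusted p = 0.108, range over 20 alternatives 0.0121 to 1), passing at a minimum count of 10 (0.0248) and without resistant HCT116 replicate 3 (0.0121). SAMD4A had 9 and 0 reads in HCT116 and 11 and 18 in Lovo (edgeR adjusted p = 0.382).

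Across all 300 circRNAs the resistance effects of the lines showed no correlation at this depth. Pearson's r across circRNAs was -0.0653 (permutation p = 0.259 over 9999 permutations of circRNAs, which are not independent replicates) and Spearman's correlation -0.0902, with the same sign in 47.7%. An unadjusted p under 0.05 in both lines was met by 3 circRNAs where chance gives 1.7: ARHGAP5 in the same direction, PRELID2 and WHSC1 in opposite directions.

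**Figure D2:**
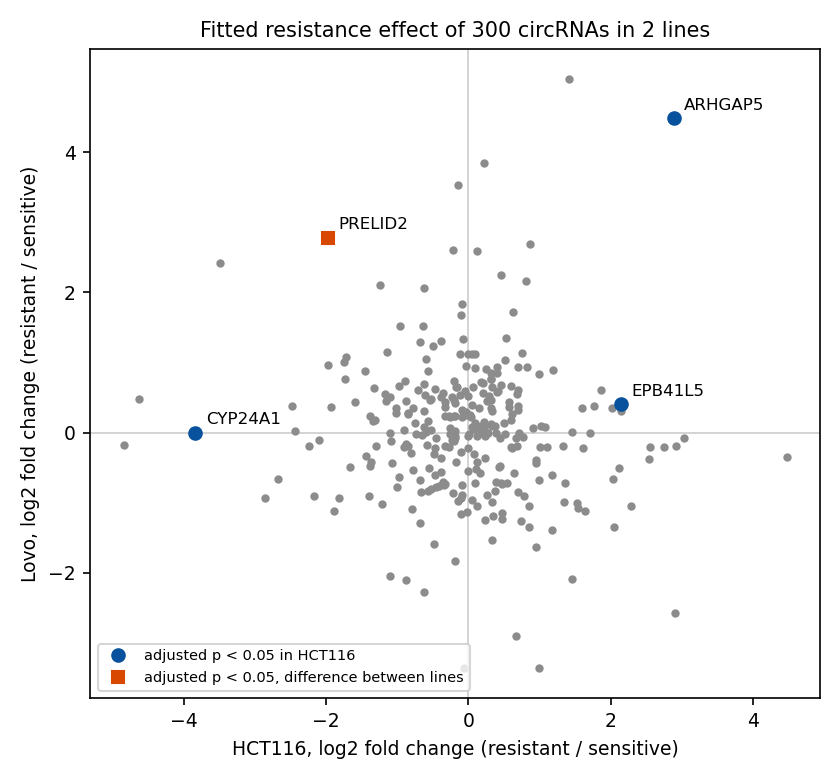
Fitted log2 fold change, resistant against sensitive, of 300 circRNAs in HCT116 (horizontal axis) and Lovo (vertical axis), with the 3 circRNAs called in HCT116 in blue and the 1 whose effect differed between the lines in orange. ARHGAP5 lies above 0 in both lines and PRELID2 on opposite sides, and fitted values of circRNAs at 0 reads in a group, such as ARHGAP5 in Lovo, are no bound on the change.

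The host gene lists fixed for this drug and tissue showed no shift that passed in camera or in summed reads. The p-values of fry are printed unadjusted. Chromatin modifiers held 12 tested circRNAs, of which 0 passed over all circRNAs in either line. An adjustment over a list alone, printed here and below, was not among the tests fixed beforehand. It was made for each list and line by itself, with no correction across lists. In HCT116 2 circRNAs of this list passed adjusted over the list alone, those of WHSC1 (edgeR adjusted p = 0.0258, and 0.129 over all tested) and of the acetyltransferase gene CREBBP (hsa_circ_0007637, 39 and 11 reads, -1.93 ± 0.71, 0.0427, and 0.196 over all tested). The demethylase gene KDM4B had 3 and 21 reads (6.34-fold, counting interval 1.89 to 33.2, edgeR adjusted p over all = 0.324), KDM4C 4 and 20 in HCT116, and KMT2C 17 and 9 in HCT116 and 15 and 10 in Lovo. As a set in HCT116 the camera p was 0.357 (adjusted p = 0.357, adjusted p = 0.361 with an estimated correlation), fry gave 0.285 for a shift in one direction and 4.00e-05 for changes in either direction. KDM4C had 14 and 6 reads in Lovo (-1.35 ± 1.01), but 13 of the 14 were in sensitive replicate 1, without which the log2 fold change turned to 1.66. In Lovo the camera p was 0.893 (fry 0.968, either direction 0.874).

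Receptor, RAS-MAPK and PI3K-mTOR signalling held 5 tested circRNAs. In HCT116 2 passed adjusted over the list alone, both of MAP3K4, a kinase upstream of JNK and p38 (edgeR adjusted p = 0.018 each, 0.196 over all tested). These were hsa_circ_0078617 with 27 and 6 reads (-2.23 ± 0.82) and hsa_circ_0078619, which lies within the first, with 11 and 0 reads, at least 2.77-fold lower. The first passed over all circRNAs in limma-voom (adjusted p = 0.03) and in edgeR without resistant replicate 2 (0.00555), which held all 6 resistant reads, so that the resistant group was then at 0, over a range of 0.00555 to 0.679 in 14 alternatives. Both stood at equal reads in the 2 Lovo states (16 and 16, 10 and 10). The circRNA of MAPK9 had 14 and 26 reads in HCT116 (0.70 ± 0.65) and 19 and 34 in Lovo (0.61 ± 0.60), and that of MET, a receptor tyrosine kinase, 68 and 65 in HCT116 and 36 and 49 in Lovo. That of MAPK8 had 15 and 12 reads in HCT116 and 6 and 4 in Lovo. The set gave a camera p of 0.088 in HCT116 (adjusted p = 0.176, adjusted p = 0.238 with an estimated correlation, fry p = 0.014, either direction 0.25) and 0.774 in Lovo (fry 0.55, either direction 1), where camera pointed up and the median fold change was -0.18.

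In HCT116 the summed reads of DNA damage response and strand break repair genes had the smallest p of the lists, with 400 reads in sensitive and 289 in resistant cells (-0.52 ± 0.18, n = 3 each, edgeR quasi-likelihood adjusted p = 0.083 over 16 lists, of which 14 had reads in HCT116). WNT signalling followed with 197 and 144 reads (-0.50 ± 0.23, edgeR adjusted p = 0.232). The list of fluoropyrimidine and folate metabolism, the pathway of the drug, had 84 and 68 reads (-0.32 ± 0.34) in HCT116 and 55 and 49 (-0.42 ± 0.38) in Lovo. Only 1 of its 71 circRNAs had enough reads for a test, and 0 were called. For the other lists in HCT116 the log2 fold change of the sum was -0.15 ± 0.36 for ABC transporters, -0.18 ± 0.21 for mismatch and base excision repair, 0.04 ± 0.20 for p53 and apoptosis and 0.05 ± 0.21 for the cell cycle. It was 0.28 ± 0.17 for EMT, adhesion and extracellular matrix, -0.12 ± 0.15 for chromatin modifiers, -0.13 ± 0.18 for splicing and circRNA biogenesis, -0.11 ± 0.23 for rRNA processing and RNA decay, -0.31 ± 0.18 for receptor signalling and 0.46 ± 0.32 for TGF-beta and BMP signalling. In Lovo the smallest adjusted p was 0.927, with -0.04 ± 0.20 for the DNA damage response, 0.15 ± 0.23 for WNT signalling, 0.28 ± 0.26 for rRNA processing and RNA decay and 0.12 ± 0.20 for EMT, adhesion and extracellular matrix. The Lovo sums of ABC transporters (-0.07 ± 0.42), mismatch and base excision repair (-0.17 ± 0.24), p53 and apoptosis (0.04 ± 0.20), the cell cycle (0.11 ± 0.20) and chromatin modifiers (-0.04 ± 0.16) also stayed close to 0. So did those of splicing factors (-0.13 ± 0.18), receptor signalling (0.03 ± 0.18) and TGF-beta and BMP signalling (0.08 ± 0.31).

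Single members of these lists mostly showed small differences. The circRNA of PTBP3, a splicing regulator (hsa_circ_0003500, chromosome 9, 115030329 to 115060196), had 4 and 21 reads in HCT116 and passed adjusted over the list alone, which held 3 tested circRNAs (2.15 ± 0.89, edgeR adjusted p = 0.0489, 0.259 over all tested). It was named after its value was seen. Outside the lists of chromatin modifiers, receptor signalling and splicing factors, and in all lists in Lovo, the count adjusted over the list alone was 0. Lists other than these named ones held at most 4 tested circRNAs, and that of ABC transporters 0, so little could be called in them. Among tested members, the circRNA of BRIP1, a helicase of the DNA damage response, had 26 and 15 reads in HCT116 and 5 and 10 in Lovo, that of PMS1, a mismatch repair protein, 54 and 53 and 21 and 23, and that of MTHFD2L, a mitochondrial folate enzyme, 11 and 15 and 5 and 11. These 3 were also chosen after their values were seen. Intestinal epithelium markers had 34 and 37 reads in HCT116 (0.09 ± 0.46) and 59 and 64 in Lovo (-0.14 ± 0.38). Fibroblast markers had 0 reads in HCT116 and 5 and 0 in Lovo, endothelial markers 0 in HCT116 and 1 and 1 in Lovo, and immune cell markers had 0 circRNAs in the table.

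**Figure D3:**
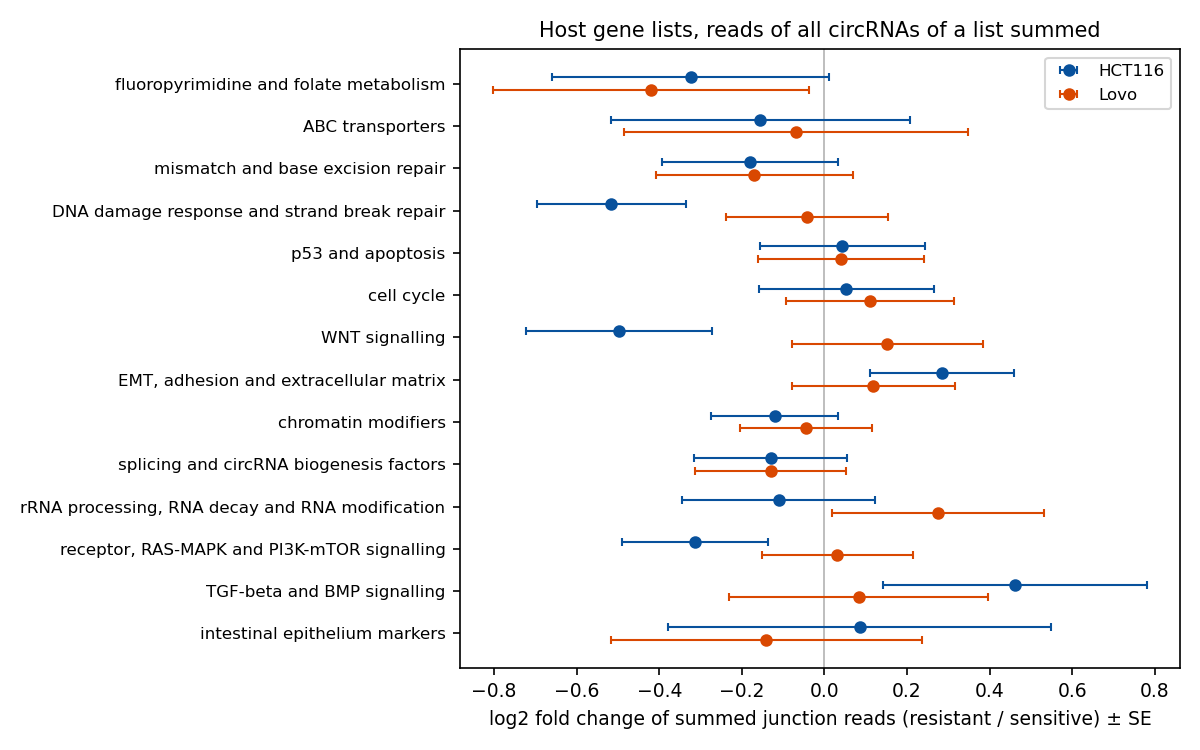
Log2 fold change, resistant against sensitive, of the summed junction reads of all circRNAs hosted by 14 gene lists (horizontal axis, points with SE) in HCT116 (blue) and Lovo (orange). In HCT116 the DNA damage response list stands at -0.52 ± 0.18 and WNT signalling at -0.50 ± 0.23, and neither passed after adjustment.

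No chromosome passed in either line, in camera with the preset or the estimated correlation (21 sets) or in summed reads (26 sets). In HCT116 the smallest camera p-values belonged to chromosome 16 (p = 0.0328, adjusted p = 0.425, p = 0.0558 with an estimated correlation, fry p = 0.0026), with 9 of 10 circRNAs below 0, and chromosome 6 (p = 0.0404, adjusted p = 0.425, p = 0.121 with an estimated correlation), with 13 of 16 below 0. For changes in either direction fry gave its smallest unadjusted p in HCT116 for chromosomes 20 (1.81e-09), 14 (5.42e-07), 2 (0.000871) and 6 (0.0026). The first 3 of these hold the called circRNAs of CYP24A1, ARHGAP5 and EPB41L5. In Lovo its smallest were 0.00303 for chromosome 7 and 0.00946 for chromosome 5. On chromosome 16, besides CREBBP, the circRNA of NMRAL1 had 24 and 12 reads and that of SRCAP, a chromatin remodeller, 25 and 14. In Lovo the smallest were chromosomes 1 and 11 (camera adjusted p = 0.78 for both). The Lovo circRNAs with the smallest p on chromosome 1 were, besides MAN1A2, those of DNAH14 (0 and 4 reads, too few to bound a change) and OMA1 (12 and 2 reads, 6.96-fold lower, counting interval 1.55 to 64.0). On chromosome 11 they were those of ZBTB44 (31 and 59 reads), HIPK3 (121 and 176 reads) and PICALM (5 and 13 reads). The part of 18p that holds TYMS gave a camera p of 0.816 in HCT116 and 0.8 in Lovo over 5 circRNAs.

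Circular RNAs known from other work, fixed by circBase identifier, gave no call. That of HIPK3 (hsa_circ_0000284) had a log2 fold change of -0.08 ± 0.28 in HCT116 and 0.33 ± 0.27 in Lovo, near 0 and of either sign across alternatives in HCT116 (0.0163 with total counts). That of PVT1, a long non-coding RNA gene (hsa_circ_0001821), had 27 and 48 reads in HCT116 (0.70 ± 0.45) and 65 and 42 in Lovo (-0.84 ± 0.41, edgeR adjusted p = 0.662). ZNF609 (hsa_circ_0000615) had 8 and 16 reads in HCT116 (0.85 ± 0.82) and 27 and 15 in Lovo (-1.05 ± 0.72), NFATC3 (hsa_circ_0000711) 27 and 28 and 12 and 16, and hsa_circ_0000567, which the table assigns to SETD3, 59 and 54 and 17 and 23. Too few reads for a test were found for circRNAs of FBXW7 (6 and 9 in HCT116, 4 and 10 in Lovo), FOXO3 (5 and 3, 4 and 2), SMARCA5 (3 and 1, 0 and 1), ITCH (2 and 2, 0 and 0), SHPRH (3 and 4, 0 and 0), CCDC66 (0 and 11, 3 and 1) and CDR1 (0 and 3, 0 and 0). Of genes of 5-Fu handling, 3 circRNAs of TYMS, the drug's target, had 4 and 0 reads in HCT116 and 0 and 3 in Lovo, 2 of UMPS had 14 and 4 and 5 and 10, and those of ABCB1 and ENOSF1 had at most 2 reads in a group. DPYD and TYMP had 0 circRNAs in the table, and the fixed circRNAs of MTO1 and PRKDC had no entry in it. None of the circRNAs of 5-Fu handling genes had enough reads for a test.

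Between the parental lines 43 of 300 circRNAs differed, 26 higher and 17 lower in HCT116. The junction assigned to MAVS, an antiviral signalling adaptor (no circBase record, chromosome 20, 3835205 to 3870375), had 104 reads in sensitive HCT116 and 0 in sensitive Lovo, at least 23.7-fold higher (edgeR quasi-likelihood adjusted p = 1.69e-18). CYP24A1 (110 and 0 reads) was at least 25.1-fold and the circRNA of the long non-coding RNA gene FIRRE (hsa_circ_0001944, 36 and 0 reads) at least 7.94-fold higher in HCT116. The circRNA of ARHGAP12 was higher by 1.72 ± 0.32 log2 units (6277 ± 1411 against 1909 ± 590 CPM, SD, n = 3 each, edgeR adjusted p = 3.91e-06) and that of G073721 by 1.76 ± 0.35 (edgeR adjusted p = 1.92e-05). Higher in Lovo were a junction assigned to DSG3, a desmosomal cadherin (no circBase record, chromosome 18, 28968330 to 29049312, 0 and 71 reads, at least 21.9-fold), and the circRNAs of ABR (0 and 61 reads, at least 18.7-fold), TRABD2A (0 and 63 reads, at least 19.4-fold) and the protein kinase gene PRKD3 (-2.99 ± 0.53, 8 and 58 reads, edgeR adjusted p = 1.07e-06). The uncertain HLA-C junction stood at -3.80 ± 0.61 (5 and 64 reads, edgeR adjusted p = 2.61e-08).

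The split of the parental calls moved with the scaling, from 26 higher and 17 lower with TMM to 19 higher and 26 lower with total counts alone, while the 10 circRNAs named for the parental lines kept their direction in every alternative. Relative to TMM, total counts shifted the median log2 fold change by -0.24 between the parental lines and 0.15 for the difference of effects, and DESeq2's size factors shifted it by -0.13 in Lovo and 0.18 for the difference of effects. Without a filter ARHGAP12 (edgeR adjusted p = 0.11) and G073721 (edgeR adjusted p = 0.1) lost their calls and 14 circRNAs were called. With the replicate number as a block fewer circRNAs were called as well, and FIRRE lost its call (edgeR adjusted p = 0.152). The ranges of adjusted p over 15 alternatives were 8.01e-08 to 0.11 for ARHGAP12 and 3.86e-06 to 0.1 for G073721.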

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

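Chosen only after the result was seen were the tests of other junctions of the host genes, of CYP24A1 and of ARHGAP5 with EPB41L5 without the deviating library, of circBase records, and of HCT116 libraries thinned to the Lovo depth.

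The change of the PRELID2 circRNA between sensitive and resistant libraries differed between the lines, by the test of the difference itself, with -4.75 log2 units (HCT116 minus Lovo, edgeR adjusted p = 0.0038). Of 200 possible splits of the libraries within both lines 100 were drawn, and 5 of them, the real one included, gave at least 1 call (highest other 2), so chance was not excluded for this count.

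The other counts of calls were set against the 10 splits of their 6 libraries, which are too few for a share under 0.05. Counts as large came from 1 of 10 splits for HCT116 circRNAs (real 3, highest other 2), for HCT116 host gene sums (real 3, highest other 0) and for the parental lines (real 43, highest other 0). They came from 10 of 10 splits, since the real count was 0, for Lovo circRNAs (highest other 0), Lovo host gene sums (1), the lists in HCT116 (0) and Lovo (0), and the chromosomes in HCT116 (0) and Lovo (1).

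A first pattern was the 3 circRNAs called in HCT116, of which 1 kept its call without resistant replicate 1, the library that lay apart on the second principal component. That library as the cause was excluded for CYP24A1, at -3.90 ± 0.66 and an edgeR adjusted p of 1.23e-06 without it. Without it the calls of ARHGAP5 (edgeR adjusted p = 0.0727) and EPB41L5 (edgeR adjusted p = 0.222) ended, on fewer samples. Their estimates did not rest on that library alone: ARHGAP5 stood at 2.89 ± 0.65 with it and 2.66 ± 0.77 without, and EPB41L5 at 2.14 ± 0.57 and 1.97 ± 0.65. Both stayed over 2 standard errors above 0. That limit was set afterwards for circRNAs picked by their calls, so it cannot exclude the library as a cause of these 2 calls. A change of the whole host gene may account for ARHGAP5, whose 4 other junctions rose 3.06-fold together (8 to 27 reads, counting interval 1.35 to 7.79). The same holds for CYP24A1, whose 1 other junction went from 5 reads to 0 (ratio 0, upper limit 0.989). For EPB41L5 the 4 and 7 reads of 3 other junctions cannot tell (1.59-fold, 0.403 to 7.38). They leave out 1 junction that ends within 5 bases of the called one. All these are back-splice junctions and linear RNA was not analysed. A change of the host gene therefore cannot be told apart from a change of circle formation across the gene. An effect of the selection with 5-Fu itself stays open and untested.

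A second pattern was that circRNAs were called in HCT116 and none in Lovo, a difference that was tested per circRNA only, by the difference of effects. HCT116 libraries thinned to the Lovo totals still gave a median of 3 calls over 20 draws (1 to 5), so changes as large as those in HCT116 could be called at that depth. Lower depth of the Lovo libraries was not excluded as a cause. The draws re-use the libraries in which the changes were first called, and CYP24A1 had no reads in Lovo at all. A difference between the lines in their response as a whole was not tested and stays open.

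A last pattern was that 12 circRNAs differing between the parental lines had reads in only one of them, 8 in HCT116 and 4 in Lovo. Of these, 4 had no circBase record (33.3%; SPAG9, DSG3, USP34 and MAVS) against 6 of 288 other tested circRNAs (2.08%, odds ratio 22.7, Fisher's exact one-sided p = 0.000275), and all 4 spanned over 20000 bases, as did 9 of all 12 and 48 of the 288 others. Such junctions may mark rearranged DNA, such as a tandem duplication carried by one line, or misplaced reads rather than back-splicing, which no test here decides. A silent host gene in the other line cannot be told apart, since the median of the reads of other junctions there was 0.5 and 5 of 12 hosts had over 3. A difference in splicing between the lines stays open and untested.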

How the results depend on the processing

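Merging of close junctions, thinning to the Lovo depth and summed reads of sets were chosen only after the result was seen. Of 224 comparisons of a count of calls or a library measure with an alternative 27 moved, by over 1.5 times for calls and by at least the larger group SD for library measures, and of 854 values of named circRNAs 20 passed only in the alternative, 14 lost the threshold and 13 changed sign. The CYP24A1 circRNA passed in all 15 alternatives in HCT116. Lists and chromosomes stayed at 0 in all alternatives run for camera and in summed reads. The p-values of fry were not adjusted and were not among these counts. Against 3 HCT116 circRNA calls there was 1 without a filter, 6 in limma-voom and 29 at an unadjusted p under 0.05 with a 2-fold change. Against 0 in Lovo there was 1 with the 6 libraries alone, 1 after merging junctions and 14 unadjusted. Against 1 for the difference of effects there were 2 at a minimum count of 10, 2 in limma-voom and 0 without a filter. Against 43 between the parental lines there were 14 without a filter and 86 unadjusted. Against 3 HCT116 host gene sums there were 5 in limma-voom, 6 with 6 libraries alone and 34 unadjusted, and against 0 in Lovo 24 unadjusted. Fewer calls without a filter come with more features tested; the cause of the others was not tested. Detected circRNAs in resistant minus sensitive Lovo went from 149.3 to -69.1 at 2 counts and 395.3 without thinning, and in HCT116, within that SD, from 10.1 to -49.2 and 6. The difference in exonic share went from -0.880 to -0.372 in HCT116 and from 0.910 to 0.394 in Lovo as a share of circRNAs, also within it.

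Pairing of the libraries by replicate number was not seen: same-numbered libraries had residual correlations of -0.0448 to 0.0625. Counting noise at these low counts could hide a pairing, so it is not excluded. With the replicate number as a block 18 parental circRNAs were called, FIRRE losing its call (adjusted p = 0.152, range over 14 alternatives 2.37e-06 to 0.152), with fewer residual degrees of freedom, and the other counts were unchanged. Leaving out 1 library gave 1 to 5 HCT116 calls, 0 to 3 for the difference of effects (0 without sensitive HCT116 replicate 1 or resistant Lovo replicate 3), 30 to 48 parental calls, 2 to 3 HCT116 and 0 to 1 Lovo host gene sums. Signs changed only for values that did not pass. HIPK3 in HCT116 was 0.0163 with total counts and -0.19 to 0.20 with 1 library left out. With 1 library left out SETD3 ranged from -0.41 to 0.0169, NFATC3 from -0.68 to 0.13 and ZNF609 from -0.0273 to 2.11 in HCT116, and NFATC3 from -0.49 to 0.93, KDM4C from -3.02 to 1.66, MAPK8 from -4.21 to 3.52 and MET from -0.19 to 0.74 in Lovo. The alternative pseudocount was for normalized values and was not run, since the table holds counts. The reach of the test was uneven: an 8-fold decrease was recovered in 36% of simulated HCT116 cases and an 8-fold increase in 98%.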

Other observations

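The circRNAs read in one parental line alone were still read in the resistant cells of that line, at numbers that differed. The MAVS junction had 104 reads in sensitive and 153 in resistant HCT116, that of SPAG9, a JNK scaffold protein, 18 and 33, and that of FIRRE 36 and 46, and that of USP34 23 and 89, each with 0 in every Lovo library. In Lovo the DSG3 junction had 71 and 56 reads and that of NAV3, a neuron navigator protein, 22 and 25, with 0 in HCT116, while ABR had 61 and 93 and TRABD2A 63 and 68, with 1 and 3 reads in resistant HCT116. CYP24A1 went from 110 to 8 reads in HCT116 and ARHGAP5 from 9 to 77. DNAH14 had 23 and 22 reads in HCT116 and 0 and 4 in Lovo, and that of the chromatin ATPase gene ATAD2 18 and 23 against 0 and 5, so that with ARHGAP5 (0 and 8) 3 of the 8 HCT116 junctions had reads in resistant Lovo. SPAG9, NAV3 and ATAD2 were chosen after their values were seen.

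Merging junctions with ends within 5 bases was chosen only after the result was seen and joined 2 junctions of EPB41L5. The merged EPB41L5 circRNA rose by 1.899 ± 0.467 log2 units in HCT116 (edgeR quasi-likelihood adjusted p = 0.00502, n = 3 each).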
